A study of Mus musculus with 2 samples.

How the data were processed

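Total RNA of mouse embryonic stem cell derivatives was measured on 2 one-colour oligonucleotide arrays, 1 array per group. Embryonic stem cells had been grown on OP9 stromal cells, a mouse bone marrow stromal line that promotes blood formation, and cells carrying Flk-1 on their surface had been collected by fluorescence-activated sorting. Flk-1 is the product of Kdr and marks early mesoderm. Per the labels' protocols, RNA was extracted with a micro-column kit, amplified with an amino allyl amplification kit, coupled to Cy5 and hybridised to a TORAY array. The labels give 350000 cells for the revertant sample and 300000 for the gene-trapped sample. The sample descriptions give day 4.5, whereas the treatment protocol gives a coculture of 4 days.

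The deposited scanner files hold a linear spot intensity, the median over the spot without background subtraction, which per the file headers was read at 3 scanner gains and joined by least squares. The scanner model and its software are not given in the sources used here. The authors also deposited a table of processed values, again as linear intensity. Set against the scanner values, that table followed a straight line: the spot intensity less about the mean of the blank spots, divided by 1 constant per array that puts the median at 25. Each of its columns has a median of 25, its direction is that of the scanner values, and the reason for its empty cells near the blank level is not stated.

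Each array has 27456 spots, of which 2736 are blank and 96 are negative controls. The mean blank signal was 22.5 on the revertant array and 20.1 on the gene-trapped array, and a probe was taken as above background when its signal exceeded the blank mean by more than 2 SD. By that limit 19704 probes (83.9%) were above background on the revertant array and 19389 (82.6%) on the gene-trapped array. The 2 kinds of positive control, with 24 spots each, had SDs of the log2 ratio between arrays of 0.108 and 0.0989, which is a technical spread between spots and not between cultures. There were no replicates, so the number of arrays limits the precision of every difference, and no p-value or standard error is given.

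Intensities were corrected with the normexp model (offset 50) of limma 3.58.1 in R 4.3.3, quantile-normalized between the arrays and put on the log2 scale. The scanner's local background column was not subtracted in the main setting, since it followed spot brightness. The offset makes differences of dim genes smaller than the ratio of their signals, so folds are those of normalized signals. Differences are gene-trapped minus revertant, and a gene was counted as higher or lower at a fixed size of at least 2-fold. Control spots and 2 probes with a quality flag were left out. Tables were summarised with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

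Gene names came from the platform annotation: 16631 of 23473 probes have 1 symbol, 6842 have none and 0 have several. Of the probes with a symbol, 12622 carry a current symbol and 16569 match a current symbol or synonym in a RefSeq gene table of assembly GRCm38.p6. Names are printed as the annotation gives them, which can be old. No genome build is named in the files, so no coordinates are given. Where a gene had several probes, the probe with the highest mean log2 signal was used. Of 3 genes with at least 2-fold differences and several probes above background, 2 had the same sign at every probe. A gene above background on 1 array only has a bound: its signal over the higher of the dim probe's own signal and the lowest signal among genes above background on the dim array.

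The 26 gene lists were described by the median log2 difference of members above background on both arrays, with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. The percentile describes these 2 libraries only. The named genes are AU019823 and Kdr, the 12 genes with the largest differences in each direction, up to 4 members of each list with the largest absolute difference, list members above background on 1 array only, and up to 5 genes each way with the largest bounds. The 12 in each direction needed a mean signal at or above the median and a 2-fold difference also under median scaling, and clone or model names were counted without being named. Groups, lists, the 2-fold rule, the naming rule and 10 alternatives were fixed before the data were examined. The decision to leave the local background column out, and 2 further alternatives, subtraction of that column and a correction for spot position, were chosen after the data had been seen. The alternatives fixed in advance were median scaling, 75th percentile scaling, cyclic loess, offset 16 and no background correction. They also included no filter, a stricter filter, the mean of a gene's probes, the authors' table and the mean of a list. Median and 75th percentile scaling differ only by a constant added to every difference, so each list has the same percentile under both. In counts of settings they are therefore not separate checks of a list's percentile.

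The procedure was tested on simulated data for the gene-trapped against revertant comparison, with noise of SD 0.1 on each array and 200 of 18118 probes changed. It counted 96% of probes with a true log2 difference of 2 and 72% at 1.5, but 60% at -2 and 36% at -1.5. The changed probes were drawn only from those well above the blank mean on the revertant array, so these rates do not cover dimmer probes. No unchanged probe of 17918 was counted (0), which covers technical noise only. The simulated SD is that of 1 array, whereas the control spot SDs are of the ratio between arrays. Noise in a simulated difference is therefore larger than 0.1, but still below the spread of 0.34 among genes as bright as AU019823. A planted list had percentile 0 and an unchanged list 16.6.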

Results

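Gene expression was measured in Flk-1-positive early mesodermal cells from mouse embryonic stem cells in which the gene AU019823 was disrupted on both alleles by a gene trap, an inserted cassette that interrupts transcripts. The comparison sample came from revertant cells, whose genotype the labels describe as nearly that of the wild type. There was 1 array per group and no replicate, so each difference compares these 2 libraries and has no replicate check. The samples carry different codes in the labels whose meaning is not stated, and if these are clones, clone and genotype cannot be told apart. The median probe signal was 47.5 on the revertant array and 38.6 on the gene-trapped array.

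The disrupted gene itself had a log2 signal of 8.89 in revertant and 8.50 in gene-trapped cells, a log2 difference of -0.39 (probe M400006970). AU019823 is named Nkapd1 in the RefSeq gene table. Its difference lay at percentile 13.7 among genes of similar brightness, whose spread was 0.34, so it was not set apart from them. The place of the probe relative to the trap is unknown, and its value therefore does not check the labels. Kdr, the gene of the sorted surface protein and a receptor for vascular endothelial growth factor, had a log2 difference of -0.65 (1.57-fold lower), at percentile 7.68.

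Of 16388 named genes, 13714 were above background on both arrays, and 47 of these were at least 2-fold higher and 149 at least 2-fold lower in gene-trapped cells. Together they make 196 genes or 1.43%, of which 14 have clone or model names. The largest positive difference, 2.73, belonged to 1700007K13Rik, a clone name outside the naming rule that was singled out after its value was seen. Among genes within the rule, Dcxr, a carbonyl reductase, was highest at 2.22 (4.64-fold), followed by the streak transcription factor Mixl1 at 1.99 and the cytochrome c oxidase subunit gene Cox6b2 at 1.97. Tdgf1, a co-receptor for Nodal, had 1.89, the cyclin gene Ccng1 1.85, Phlda3 1.74, the protease inhibitor gene Serpine2 1.64, Ddit4l 1.63, Arrdc4 1.53, the cell cycle inhibitor gene Cdkn1a 1.5, the homeobox gene Gsc 1.5 and the cap-binding protein gene Ncbp2 1.35. The lowest was Slc7a3, a cationic amino acid transporter, at -3.09 (8.52-fold lower). Derl3, which acts in degradation of misfolded endoplasmic reticulum proteins, had -2.56, cardiac troponin T gene Tnnt2 -2.37, Sdf2l1 -2.31, the pseudokinase gene Trib3 -2.31 and the glucose transporter gene Slc2a3 -2.19. Herpud1 had -2.16, the phosphofructokinase gene Pfkp -2.13, the neutral amino acid transporter gene Slc1a4 -2.12, the sterol reductase gene Tm7sf2 -2.03, Stc2 -2.02 and the endoplasmic reticulum oxidase gene Ero1l -2.0. With the scanner's local background subtracted, a setting added after the data were seen, 272 genes were higher and 183 lower, and Slc7a3 had 0.12. The authors' table gave 284 higher and 570 lower, but over 14163 genes with a value in both of its columns, not the 13714 above background here. Folds of dim genes were larger there and their order differed: Derl3 was 35.3-fold lower, Slc7a3 30.1-fold and Stc2 18.9-fold, and Ddit4l was 12.6-fold higher, against 5.89, 8.52, 4.07 and 3.09 in the main setting.

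**Figure D1:**
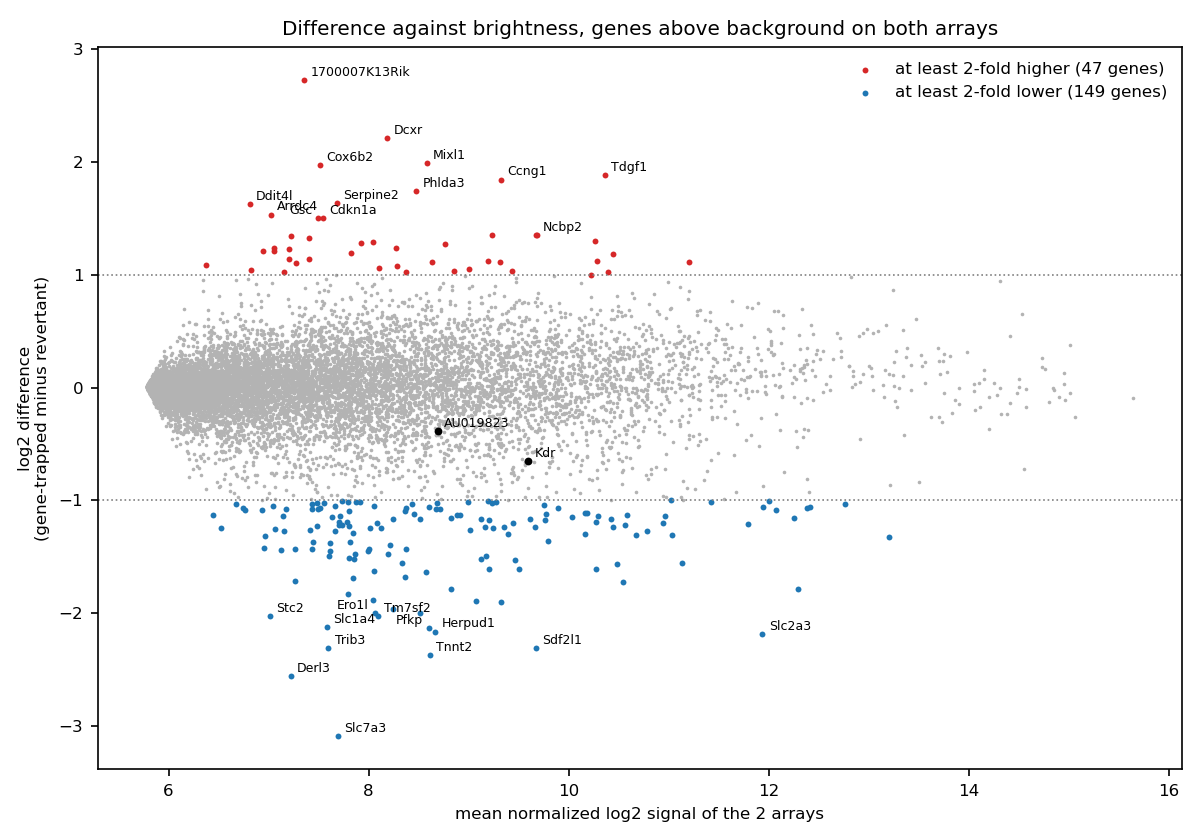
Log2 difference (gene-trapped minus revertant) against mean normalized log2 signal for 13714 genes above background on both arrays, 1 point per gene, with dotted lines at 2-fold. Red marks the 47 higher and blue the 149 lower genes, and black marks AU019823 (-0.39) and Kdr (-0.65), which lie between the lines.

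The p53 target and apoptosis list was higher in gene-trapped cells. Of its 24 measured members, 9 were at least 2-fold higher, 0 were lower and 22 lay above 0. Ccng1 had a log2 difference of 1.85, Phlda3 1.74, Ddit4l 1.63 and Cdkn1a 1.5. Ccng1, Phlda3 and Cdkn1a are known transcriptional targets of p53. The list's median was 0.88, at percentile 100 of matched random lists.

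Genes of hypoxia and glycolysis were lower in gene-trapped cells, with 12 of 24 members at least 2-fold lower and 0 higher. Slc2a3 had -2.19, Pfkp -2.13, the collagen prolyl hydroxylase gene P4ha2 -1.97 and the glucose transporter gene Slc2a1 -1.79. The median was -1.02, at percentile 0. The list of unfolded protein and amino acid stress was lower to a similar size, with a median of -1.04 at percentile 0 and 10 of 19 members at least 2-fold lower. Its leading members were Sdf2l1 at -2.31, Trib3 at -2.31, Herpud1 at -2.16 and the stress transcription factor gene Ddit3 at -1.89. Among 12 reference genes the median was -0.08 (percentile 7.87), but the glycolytic enzyme genes Pgk1 and Gapdh had -1.33 and -1.09. Pgk1 stands on both the hypoxia and the reference list.

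**Figure D2:**
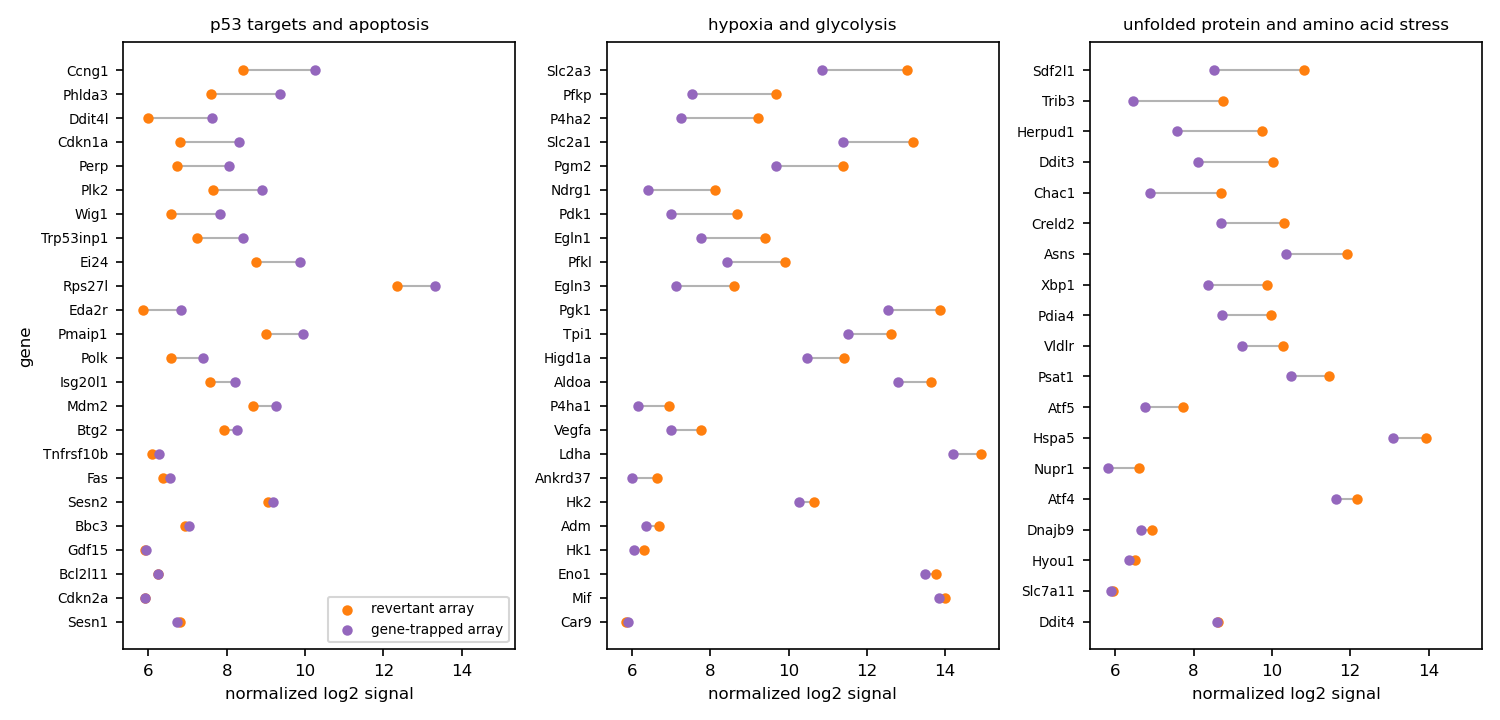
Normalized log2 signal of each measured member of 3 gene lists on the revertant array (orange) and the gene-trapped array (purple), 1 line per gene. In the p53 panel 22 of 24 genes have the purple point to the right, and in the hypoxia panel 12 of 24 genes lie at least 2-fold to the left.

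The list of primitive streak and nascent mesoderm genes, which mark the cells that form mesoderm, had a higher median in gene-trapped cells, although few members passed 2-fold. Mixl1 had 1.99, Gsc 1.5, Lhx1 0.86 and T, the brachyury gene, 0.76. Wnt5a had -0.63. The median of 17 members was 0.39 at percentile 100, with 14 above 0 and 2 at least 2-fold higher. The offset makes differences of dim genes smaller, which lowers such counts. In the authors' table the median was 0.65, and T (2.06-fold) and Lhx1 (2.11-fold) also passed 2-fold. Lateral plate and early vascular mesoderm genes went both ways. Etv2, a transcription factor needed for blood and endothelium, had 1.30, whereas Snai2 had -1.42, Tbx20 -0.70 and Kdr -0.65. The median of 19 members was 0.06 (percentile 70.6). Paraxial mesoderm genes had a median of 0.02 over 12 members (percentile 72.9), with the Notch ligand gene Dll3 at 0.96 and Dll1 at 0.31.

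The endothelial and hematopoietic lists had lower medians in gene-trapped cells, although few members passed 2-fold in the main setting and some were higher. Many members are dim, so the offset lowers these counts too. In the authors' table the endothelial median was -0.79 and the hematopoietic median -0.64. The median of 25 endothelial genes was -0.22 at percentile 0, with Flt1 at -1.53, Tek at -1.32, Pecam1 at -1.27 and Ramp2 at -0.76. Flt1 and Tek encode receptors of vascular growth factors, and 3 members were at least 2-fold lower while 4 lay above 0, Eng at 0.72 and Sox7 at 0.28 among them. The 25 hematopoietic transcription factor and receptor genes had a median of -0.24 at percentile 0. The erythropoietin receptor gene Epor, at -1.09, was the 1 member at least 2-fold lower in the main setting. Gata1 had -0.77, Itga2b -0.72 and Tal1 -0.69. More members passed 2-fold in the authors' table, among them Nfe2 (7.67-fold lower) and Itga2b (7.41-fold lower). Their raw gene-trapped signals, 23.3 and 25.4, lay near that array's background limit of 22.3, so the size of these folds is uncertain. Of the hematopoietic members 6 lay above 0, Runx1 being highest at 0.25. Erythroid genes had a median of -0.16 over 9 members (percentile 2.11), with Blvrb at -0.64, Cpox at -0.46, Fech at -0.44 and Alas2 at -0.34, and kept a place outside the central 95% of random lists in 6 of 11 other settings. Cardiac genes had a median of -0.09 over 13 members (percentile 1.30) and kept that place in 8 of 11 settings. Tnnt2 had -2.37, Tnni1 -1.27, Myl4 -0.87 and Smarcd3 -0.78, and Tnni1 turned to 0.14 with the local background subtracted.

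Markers of other cell types that the culture or gate could hold did not share 1 direction. The OP9 stromal and fibroblast list had a median of -0.06 over 28 members (percentile 0.43), which turned to 0.026 under median scaling and 0.10 under 75th percentile scaling. These scalings put the median of all genes at 0.074 and 0.15, so the list stayed below the typical gene, at percentile 6.66 in both. The collagen genes Col5a1 and Col1a1 had -1.61 and -1.49, smooth muscle actin gene Acta2 -1.30 and Col3a1 -0.79. Neuroectoderm genes had a median of 0.04 over 12 members (percentile 82.1), with Otx2 at 1.29, Zic2 at 0.58, Fabp7 at 0.47 and Tubb3 at -0.42. Endoderm genes had -0.02 over 12 members (percentile 14.6), with Trf at -0.47, Sox7 at 0.28, Dab2 at -0.23 and Tacstd1 at -0.17. Macrophage and mast cell genes had 0.00 over 8 members (percentile 49.2), with no absolute difference above that of Laptm5 at -0.21. Pluripotency genes had a median of 0.03 over 21 members (percentile 88.7), although Tdgf1 had 1.89 and Dppa5 1.21. Klf2 had -0.43 and Klf5 0.40. Dppa5 had -0.075 with the local background subtracted.

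Proliferation genes had a median of 0.24 over 26 members (percentile 99.1), and 0 were at least 2-fold apart. The ribonucleotide reductase gene Rrm2 had 0.93, Ccne1 0.90, Ccne2 0.82 and the mitotic checkpoint gene Bub1 -0.75. Correction for spot position brought the median to 0.18, inside the central 95% of random lists. Imprinted genes had a median of -0.15 over 22 members (percentile 0.07), with the growth factor gene Igf2 at -1.07, Sgce at -0.96, Igf2r at -0.82 and Cdkn1c at -0.82. That place was kept in 10 of 11 settings. WNT and Notch targets (0.12 over 15 members, percentile 99.8) and HOX genes (0.06 over 23 members, percentile 99.7) kept their places in 4 and 6 of 11 settings. Dkk1 had 0.47, Lef1 0.38 and Hey2 -0.27, and of the HOX genes Hoxb6 had 0.36 and Hoxb1 -0.49.

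The remaining lists lay within the central 95% of random lists in the main setting, but interferon response genes did so in 6 of 11 other settings, pre-mRNA splicing genes in 8 and ribosomal protein genes in 9. Immediate early genes had a median of 0.15 over 17 members (percentile 91.9), with Cyr61 at -1.14, Atf3 at -0.49 and Ctgf at -0.47. Interferon response genes had 0.08 over 15 members (percentile 96.8), with B2m at -0.81, Ifitm1 at 0.81 and Ifitm3 at 0.71. Targets of BMP and TGF-beta had 0.09 over 13 members (percentile 83.3), with Id4 at 0.74, Id1 at 0.51 and Id3 at 0.50. That list also names Cripto, another name of Tdgf1 (1.89), which was not matched and is not among the 13. Pre-mRNA splicing genes had 0.15 over 31 members (percentile 96.0), with Sfrs7 at 0.77 and Sf3b2 at -0.63. Ribosomal protein genes had -0.01 over 31 members (percentile 13.1), with Rpl13a at -0.99 and Rps19 at 0.71. Sex chromosome genes had 0.12 over 5 members (percentile 81.5), with Ddx3x at -0.48. In all, 13 of 26 lists lay outside the central 95%, 5 of them high and 8 low, where 1.3 would be expected for random lists. Random lists are matched on signal alone, whereas members of a fixed list may change together. Some fixed lists also share genes, such as Pgk1 and Sox7. The 1.3 is therefore not the number to expect between cultures that differ for any other reason.

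**Figure D3:**
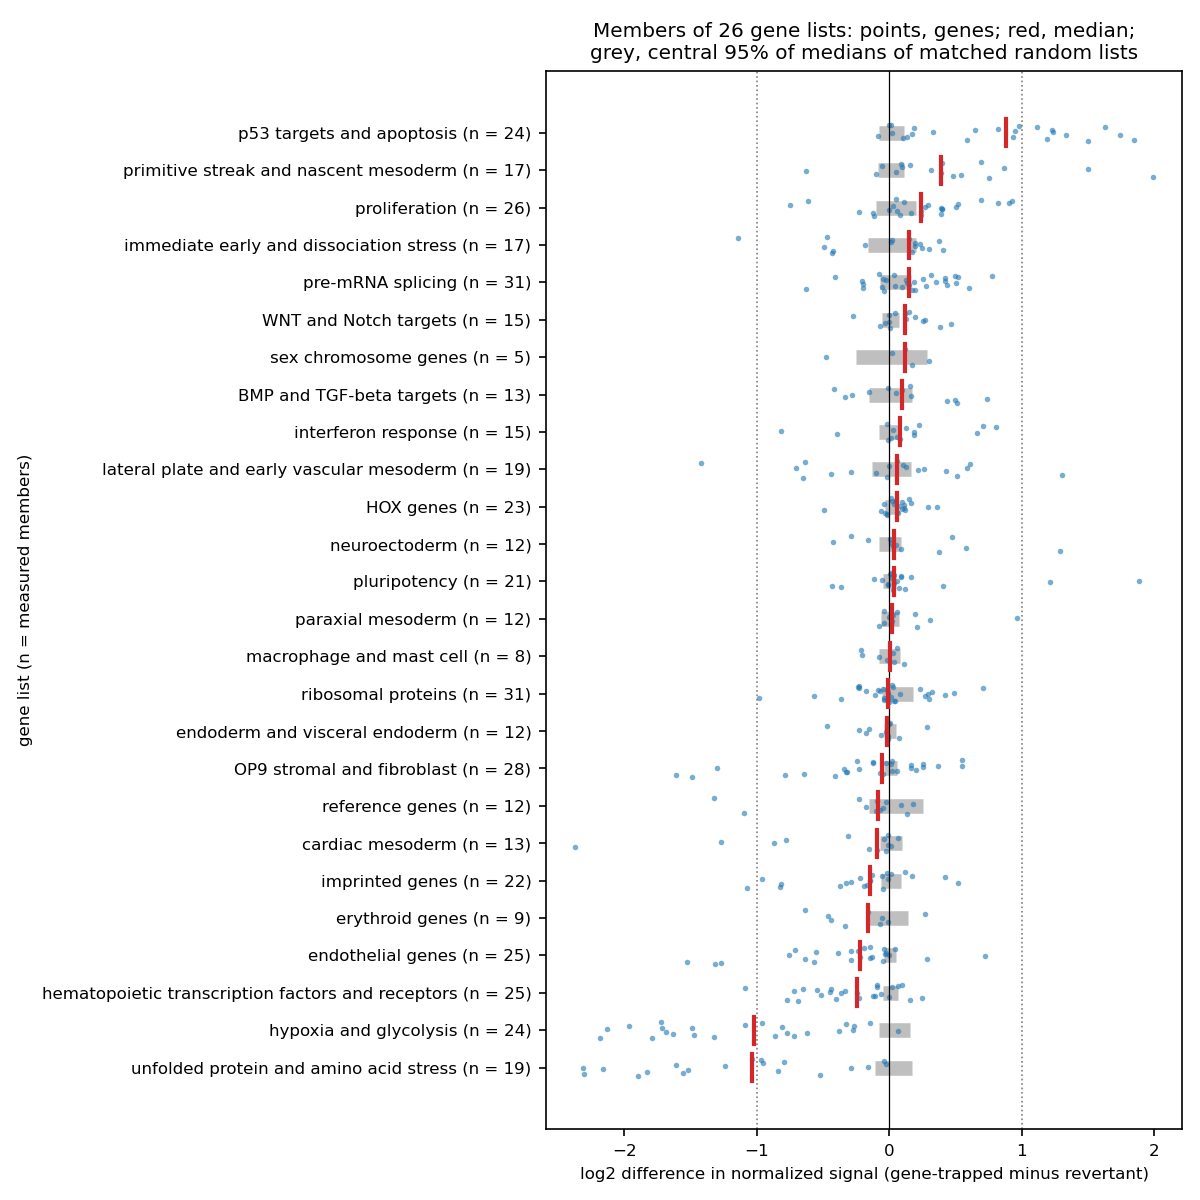
Log2 differences (gene-trapped minus revertant) of the measured members of 26 gene lists, 1 point per gene, with the list median in red and the central 95% of matched random list medians in grey. The p53 list lies farthest right (median 0.88) and the stress and hypoxia lists farthest left (-1.04 and -1.02), and the stromal median of -0.06 changes sign under median and 75th percentile scaling but stays below the median of all genes, which those scalings put at 0.074 and 0.15.

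On the revertant array 478 named genes were above background there only, and on the gene-trapped array 267. Cyb5r2 was at least 1.73-fold lower in gene-trapped cells, Aqp8 at least 1.34-fold, Ucn 1.30-fold, Abo 1.19-fold and Fmo4 1.18-fold. Olfr1506 was at least 1.32-fold higher, Olfr984 1.30-fold, V1rc23 1.27-fold, Anxa8 1.22-fold and Plcd4 1.19-fold. Of the list members, Prrx1, Meox2, Ermap, Cdh5, Six3, Mrc1, Cybb, C1qa and Hoxa13 were above background on the revertant array only. Wnt8a, Msgn1, Myl2, Cd44, Cd14, Ifit2, Hoxc6 and Hoxc8 were so on the gene-trapped array only. All these list members lay near the background limit, which was higher on the revertant array. Log2 differences ran from -0.098 (Cdh5) to -0.018 (Hoxa13) in the former group. They ran from 0.033 (Ifit2) to 0.14 (Hoxc6) in the latter. All of the latter except Hoxc6 had a higher raw signal on the revertant array. These calls therefore do not show absence from the other array.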

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

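Both results in this part were picked out after the data were seen, and no test of a cause was run on them. Probes without a gene name carried differences outside the gene comparison: 55 of 5061 such probes above background on both arrays were at least 2-fold apart, 19 higher and 36 lower in gene-trapped cells. Probe M300003686 had a log2 difference of -3.65 and M200000820 one of -2.92, the former larger in size than that of any named gene. The scanner's local background column, which the main comparison did not use, held signal well above its level at blank spots. Over the top decile of probes by brightness its median was 773 on the revertant array and 503 on the gene-trapped array, against 14.2 and 15.6 at blank spots.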

How the results depend on the processing

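Subtraction of the local background and correction for spot position were chosen after the data had been seen. No paired analysis was possible because each group has 1 array. AU019823 kept a negative difference in every setting, from -0.50 with the local background subtracted to -0.37 in the authors' table. The p53, hypoxia, stress, streak, endothelial and hematopoietic lists kept their place outside the central 95% of random lists in all 11 settings that give a median. Higher genes numbered 87 with offset 16, 83 without background correction, 272 with the local background subtracted and 284 in the authors' table, and lower genes 237, 228 and, in the authors' table, 570. The counts in the authors' table are over 14163 genes, those in the other settings named here over 13714. A smaller offset widens the folds of dim genes by construction. With the local background subtracted, 19 of the 47 higher and 75 of the 149 lower genes were still counted, and Slc7a3 turned to 0.12, Tnni1 to 0.14 and Dppa5 to -0.075. That column followed spot signal, with log2 correlations of 0.97 on the revertant and 0.96 on the gene-trapped array. Its subtraction can therefore take away signal of bright spots. Raw signals of Slc7a3 were 622 on the revertant and 35.5 on the gene-trapped array. The stromal median turned to 0.026 under median scaling and 0.10 under 75th percentile scaling, settings that move the median of all genes to 0.07 and 0.15. Against matched lists it then lay at percentile 6.66. Of the lists inside the central range, interferon response genes left it upward in 5 of 11 settings, pre-mRNA splicing genes upward in 3, neuroectoderm upward in 2 and ribosomal protein genes downward in 2, and paraxial mesoderm upward and endoderm downward in 1 each. The following medians came inside the central range. Cardiac: -0.010 (local background), -0.22 (authors' table) and -0.036 (no filter). Erythroid: -0.14 (cyclic loess), -0.17 (offset 16), -0.17 (no background correction), -0.047 (local background), -0.068 (no filter) and -0.21 (mean). Proliferation gave 0.18 after position correction, and imprinted genes -0.0078 with the local background. WNT and Notch targets gave 0.14 (median scaling), 0.21 (75th percentile), 0.023 (local background), 0.058 (position), 0.15 (authors' table), 0.057 (mean of probes), 0.19 (stricter filter) and 0.11 (mean). HOX genes gave 0.13, 0.21, 0.016, 0.16, 0.063 and 0.053 under median scaling, 75th percentile scaling, local background, authors' table, stricter filter and mean. Apart from the offset, the cause was not tested. Low signal over background limits the dim genes, HOX genes among them.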

Other observations

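The gene families named in the next paragraph, the test on bright stromal members, the comparison with other cell types and its condition on their median were chosen after results had been seen. The other tests were written before their results were seen. Of these, the tests of spot position, of background and scaling and of the stromal list reuse lists of the main comparison, whose pattern prompted them. Only the second lists and the synthetases were chosen as genes not yet examined.

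The histone, transporter and endoplasmic reticulum families were picked by symbol because members had been seen to differ, so their medians include the genes that prompted them and no percentile is given. Histone genes had a median log2 difference of 0.37 over 25 members, with 4 at least 2-fold higher and 2 lower. H2afj had 1.35, Hist1h2bk 1.28 and Hist1h4a 1.08, whereas Hist1h2bp had -1.23 and H2afx -1.08. Amino acid transporter genes had a median of -0.30 over 22 members, with Slc7a3 at -3.09 and Slc1a5 at -1.45, although Slc7a3 turned to 0.12 with the local background subtracted. Genes of endoplasmic reticulum folding and degradation had a median of -0.58 over 18 members, with Derl3 at -2.56, Pdia4 at -1.24 and Hsp90b1 at -1.03. Cytosolic aminoacyl-tRNA synthetases, several of them known targets of the transcription factor ATF4, had a median of -0.33 over 16 members at percentile 0.03. The median of 15 mitochondrial synthetases was 0.07, and the difference of the medians was -0.40 (95% bootstrap interval over genes -0.82 to -0.10). That difference is not matched for brightness: most mitochondrial synthetases were dimmer, and the offset makes their differences smaller. In the authors' table the medians were -0.46 for the cytosolic and 0.05 for the mitochondrial genes. Nars had -1.14 and Gars -0.92, whereas 3 of the 16 cytosolic genes lay above 0, Rars among them at 0.54. Lower ATF4 target expression may account for the lower cytosolic median as a hypothesis, although subtraction of the local background brought that median to 0.026.

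The higher p53 target list, with Ccng1 and Cdkn1a, kept 99.6% of its median after correction for spot position, which argues against position as its cause. Its percentile was 100 in each of 7 settings of background and scaling, with medians from 0.47 to 1.05. A second list of p53 targets that shares no member with it had a median of 0.08 over 15 members at percentile 95.77, inside the central range, but above it in 7 of 11 other settings, with medians from 0.014 to 0.38 over those 11. A broader p53 program therefore stays open and depends on the setting; Apaf1 (0.73) and Lrdd (0.81) were its highest members. The disruption of AU019823, the clone and the state of each single culture may each account for the pattern, and none of these was tested.

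The lower hypoxia list kept 101% of its median after correction for spot position, and its percentile was 0 in each of 7 settings of background and scaling, with medians from -1.48 to -0.88. A surplus of stromal cells in the revertant sample, as the whole source, was predicted to put the stromal median at or below the hypoxia median. The stromal median instead exceeded it by 0.96 (95% bootstrap interval over genes 0.57 to 1.57). For 13 bright stromal members the excess was 0.69 (0.073 to 1.77). These medians do not decide the question, since the offset shrinks dim members and the bright ones were split. Of the 13, 6 lay above 0, while Col5a1 (-1.61), Col1a1 (-1.49) and Acta2 (-1.30) were as low as the hypoxia list. The intervals describe the spread over genes and not cell content. A second list of HIF targets without shared members had a median of -0.25 over 17 members at percentile 0.01, with 3 genes at least 2-fold lower, among them Mt1 at -1.16 and Gys1 at -1.02. Lower HIF target expression is therefore a candidate explanation as a hypothesis. Oxygen, nutrients and cell density of the cultures are not in the labels and stay open beside genotype and clone, which were not tested.

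The higher streak list kept 93.1% of its median after correction for spot position. An earlier stage of the gene-trapped cells may fit the higher streak and lower vascular and blood lists: a second early list had a median of 0.19 over 12 members at percentile 99.57, and a second later list -0.05 over 15 members at percentile 1.79. This rests on small differences. The mean of the early list was -0.05, and Cfc1 had -1.21. The early list kept its place in 7 of 11 settings and the later list in 7 of the 10 that left it enough genes. Under median and 75th percentile scaling the later list lay at percentile 5.88. With the stricter filter on dim genes the early median was 0.07 over 6 members (percentile 60.64). Only 1 later member, Gng11 at 0.32, passed that filter, so the later list rests almost wholly on dim genes. A gate with more cells of other types stays open: the streak median exceeded that of 23 bright stromal, endoderm and neuroectoderm markers by 0.46 (95% bootstrap interval over genes -0.04 to 0.81). Their own median was -0.07, and the condition that it lie above 0 was added once these values were known, before which the test had been read as favouring that explanation.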
